A study of Mus musculus with 12 samples.

How the data were processed

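Total RNA of dorsal mouse epidermis (strain background C57BL/6) was sequenced in 12 libraries: 3 control and 3 double knockout (DKO) libraries at postnatal day 36 (P36) and 3 of each at 6 months. Per the labels, both genotypes carry floxed alleles of Vdr and Med1, and only the DKO mice carry a Cre transgene driven by the keratin 14 promoter, which is active in basal keratinocytes and their descendants. Per the labels' protocols, the dermal side of the skin was heated, the epidermis was peeled off with forceps and scalpel, ribosomal RNA was removed with RNase H, and 50-base single-end reads were made on a BGISEQ-500.

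The authors deposited 1 table per age with an FPKM value (fragments scaled by gene length and by the total of the library, 2 decimals) for each gene and library. The same tables hold the authors' log2 ratio of DKO over control and a p-value and q-value per gene, per the file headers; the test behind them is not given in the sources used here. Per the submitters' processing notes, HISAT2 2.1.0 and RSEM 1.2.8 were used. Those notes name the human builds GRCh38 and hg38 for these mouse samples, so no coordinates are printed. The age of a table comes from the table's name alone, and its column headers give only the genotype label and the replicate number. Entrez gene identifiers were matched to symbols in a RefSeq gene table of assembly GRCm38.p6: 19343 of 19392 identifiers with values at P36 and 17712 of 17750 at 6 months matched.

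FPKM values are not counts, and the number of reads per library is unknown. The spacing of low values could not give relative depth, because only 13 to 95 usable low genes were left per pair of libraries, so no counting interval or detection floor is given. The FPKM columns summed to between 446617 and 554382, and 12056 to 12760 genes reached 1 FPKM per library. No pair of libraries was a duplicate: at most 0.41% of genes at 1 FPKM or more had identical values in 2 libraries.

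The plan fixed before the data were examined named a count test, and limma-trend for the case that the tables held only FPKM. The second was therefore used. In R 4.3.3, limma 3.58.1 was fitted to log2(FPKM + 1), with the variance prior following mean expression, for genes with at least 1 FPKM in at least 3 libraries of the fit. Fold changes are on this log2(FPKM + 1) scale, which understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. Each age was fitted on its own 6 libraries. The difference of the genotype effect between ages (6 months minus P36) and the age effect within each genotype were fitted on all 12 libraries, over genes with values in both tables. The labels do not say that the replicates are separate animals, so p-values measure the spread between these samples.

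Data were simulated from each gene's overall mean and fitted spread, independently between genes, with 200 genes changed by known amounts. The real fits called far more genes, and recovery depends on the share of genes that change. The rates below therefore describe the simulated data and not the real fits. The changed genes were drawn only from those with a mean log2(FPKM + 1) above 2, so recovery of lower genes is unknown. On these data, the P36 fit over 12660 genes recovered 70% of genes changed by 1 on the log2 scale and 96% of those changed by 2. The 6-month fit over 12594 genes recovered 74% and 92%. False calls made up 4.43% and 3.4% of all calls. The fit of the difference between ages recovered 66% of genes changed by 1 and 10% of those changed by 0.5, with 6.9% false calls. The age fits had 5.62% false calls in control and 5.26% in DKO, so the simulated share was above 5% in the fits on all 12 libraries. Each share rests on a single simulation with few false calls, so it cannot show whether a fit truly exceeds 5%.

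Before the data were examined, 33 lists of pathway genes and cell type markers were fixed. Lists with at least 4 measured members were tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. Camera compares a list with all other genes, while fry asks only whether the members of the list shift. A camera call said to hold with fry therefore passed a different question and was not repeated. The list of mitochondrial transcripts was not used here, since none of its members was measured. Named genes follow a rule fixed at the same time: Vdr and Med1, the 8 largest called changes per direction with a curated symbol, a mean of at least 1 FPKM and groups that do not overlap, and up to 4 members per list with the smallest adjusted p, or up to 2 with the smallest p where no member passed. For the age comparisons and the difference between ages, the 4 genes with the smallest p per direction were taken. The text names part of these.

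Alternatives were a pseudocount of 0.1, no filter on low values, totals computed without keratin, keratin-associated and cornified envelope genes, the replicate number as a block, each library left out in turn, a fold threshold, and 1 joint fit of all 12 libraries. Median-ratio scaling, a filter at 5 FPKM, leaving out 2 libraries that stood apart at 6 months and leaving out a set of genes high in 1 of these libraries were added after the data were seen. Alternatives that need counts were not run. Scripts used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib for the plots.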

Results

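The series asks how the loss of the vitamin D receptor (Vdr) and of its coactivator Med1, a subunit of the Mediator complex, in keratinocytes changes gene expression in the epidermis, and its title concerns the permeability barrier. Gene expression was given as FPKM in 12 libraries, 3 per genotype and age. Libraries of one group resembled each other more than those of the other genotype at the same age: Pearson's r across genes was 0.980 to 0.988 within and 0.934 to 0.951 between genotypes at P36, and 0.969 to 0.989 within and 0.886 to 0.924 between them at 6 months. Genes are not independent replicates in these correlations. The first principal component, with 65.9% of the variance, separated the ages.

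The targeted genes were examined first. Med1 fell at P36, from 13.8 ± 0.504 FPKM in control to 9.11 ± 1.11 in the libraries labelled DKO (SD, n = 3; log2 fold change −0.55, SE 0.11, limma adjusted p = 0.0083). At 6 months its values were 14.2 ± 2.21 and 11.6 ± 0.256 FPKM (log2 fold change −0.26, adjusted p = 0.13), and with totals without keratin and cornified envelope genes it was called lower (−0.44, adjusted p = 0.0342). Vdr was not lower in the libraries labelled DKO: it stood at 68.0 ± 4.16 and 83.5 ± 6.06 FPKM at P36 (log2 fold change 0.29, SE 0.09, adjusted p = 0.0573) and at 40.5 ± 11.6 and 48.1 ± 5.49 FPKM at 6 months (0.27, SE 0.20, adjusted p = 0.302). Without control 6mo replicate 1, Vdr was called higher at 6 months (log2 fold change 0.49, adjusted p = 0.031). Since the level of Vdr goes against the label, the groups are called the libraries labelled DKO throughout, and each direction below rests on that label. An FPKM value covers the whole gene and cannot show a missing part of a transcript.

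**Figure D1:**
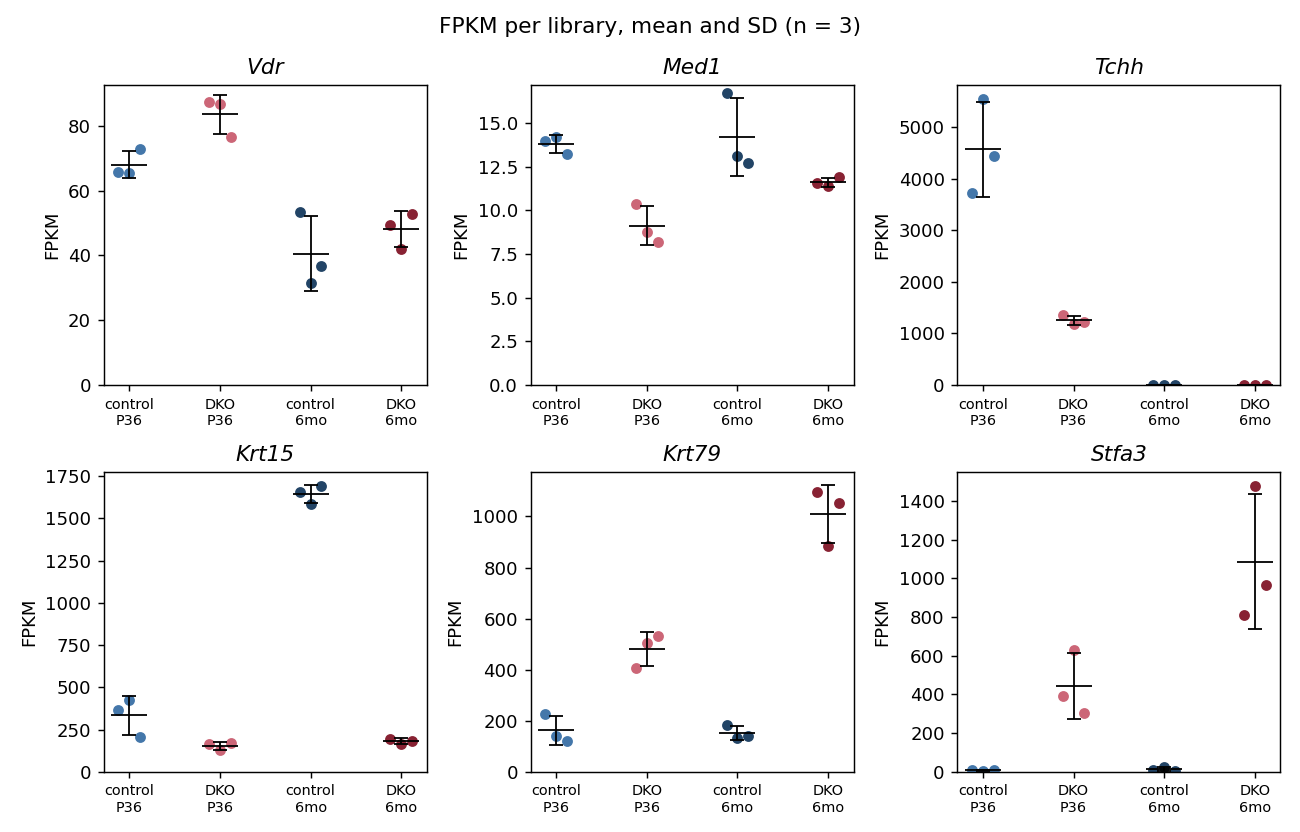
FPKM (linear axis from 0) of 6 genes in each of the 12 libraries by group; points are libraries, and bars are the mean and SD of 3. Vdr is not lower in the libraries labelled DKO, Med1 falls at P36 from 13.8 to 9.11 FPKM, Tchh is high only at P36, and Krt15 falls at 6 months from 1644 to 181 FPKM.

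At P36, hair follicle genes fell and genes of lipid synthesis, keratinocyte stress and immune cells rose in the libraries labelled DKO. No list call at P36 held with an estimated correlation (adjusted p at least 0.288). With fry, all held but those of the interferon response and melanocyte lists (adjusted p = 0.11 and 0.0887). Fry also passed lists without a camera call, such as vitamin D metabolism and response (fry adjusted p = 0.0406, camera adjusted p = 0.894). Of 49 measured genes of the hair shaft and inner root sheath, 37 fell and 0 rose, with a median log2 fold change of −1.27. Trichohyalin (Tchh), a structural protein of the inner root sheath, went from 4565 ± 914 to 1256 ± 84.2 FPKM (log2 fold change −1.84, SE 0.18). The largest rises were in the stefin A gene Stfa3, a cysteine protease inhibitor, from 7.68 ± 3.5 to 443 ± 169 FPKM (log2 fold change 5.71, SE 0.36), and in its relative Cstdc5, from 17.8 ± 10.9 to 885 ± 161 FPKM (5.74, SE 0.42). In all, 2949 of 12660 genes were called, 2275 higher and 674 lower, of which 726 and 191 changed by at least 1 on the log2 scale. Without DKO P36 replicate 2 the count was 1662, and without DKO P36 replicate 3 it was 1697. Median-ratio scaling gave 1711 higher and 966 lower, against 77.1% higher in the unscaled values.

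The hair matrix, bulge and melanocyte lists also fell at P36, while of 10 utricle and upper follicle genes 2 rose and 0 fell (median 0.40, camera adjusted p = 0.332) and of 11 dermal papilla genes 1 rose and 1 fell (median 0.01, camera adjusted p = 0.169). Without DKO P36 replicate 1 or replicate 2, only 1 dermal papilla gene was called, and it was lower. Of 27 genes of the hair matrix and its Wnt, Shh and Bmp signalling, 16 fell and 0 rose (19 fell when adjusted over the list alone; camera adjusted p = 6.74e-13, adjusted p = 0.288 with an estimated correlation). Without control P36 replicate 1, control P36 replicate 2 or DKO P36 replicate 2 only 8 were called, and 9 without DKO P36 replicate 3. Among them Bmp2 went from 12.7 to 5.14 FPKM and the homeobox gene Msx2 from 117 to 53.8 FPKM. The hair shaft list, with 45 members lower when adjusted over the list alone, had a camera adjusted p of 1.65e-31 and an adjusted p = 0.288 with an estimated correlation; 24 members were called without DKO P36 replicate 2. Its members Crym, Padi3 and Krt26 fell by 1.76, 1.61 and 1.79 on the log2 scale. Of 22 bulge and outer root sheath genes 6 fell and 2 rose, with Krt75 going from 398 to 205 FPKM (camera adjusted p = 0.00109, and adjusted p = 0.288 with an estimated correlation). Of 14 melanocyte genes 7 fell and 0 rose, with a list median of −0.89; without DKO P36 replicate 2 only 1 was called, and without control P36 replicate 3 it was 12 (adjusted p = 0.334 with an estimated correlation, and fry did not pass, adjusted p = 0.0887). The keratin-associated genes Krtap31-1 and Krtap12-1 were among the largest falls, at −4.28 and −2.48.

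Lipid genes rose at P36. Of 37 genes of ceramide synthesis and lamellar lipids, which form the barrier lipids of the cornified layer, 23 rose and 1 fell (25 and 1 adjusted over the list alone; camera adjusted p = 1.16e-05, adjusted p = 0.356 with an estimated correlation). Without DKO P36 replicate 2 or replicate 3 the called members were 15 and 14. Elovl4, an elongase of very long chain fatty acids, went from 98.6 ± 17.1 to 314 ± 82.5 FPKM, and Sptssa, a small subunit of serine palmitoyltransferase, from 62.5 ± 3.44 to 117 ± 6.92 FPKM. Of 24 genes of cholesterol synthesis and uptake 14 rose and 0 fell (20 and 0 adjusted over the list alone; adjusted p = 0.334 with an estimated correlation), among them Dhcr7, from 31.0 to 68.1 FPKM. Of 21 genes of fatty acid and glycerolipid synthesis 16 rose and 0 fell (adjusted p = 0.298 with an estimated correlation), with Acsl1 going from 14.4 to 44.2 FPKM. Of 19 sebaceous gland markers 14 rose and 1 fell (adjusted p = 0.32 with an estimated correlation), with Awat2, a wax ester synthase, rising by 2.43 on the log2 scale to 15.7 FPKM. The adipocyte list, whose cells also make lipid, rose in the same libraries (9 of 11, adjusted p = 0.298 with an estimated correlation). Leaving out the genes at least 1 higher on the log2 scale in DKO 6mo replicate 3 than in the other libraries labelled DKO at 6 months, which takes out list members, left 3 called adipocyte genes.

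Differentiation genes moved both ways at P36. Of 50 cornified envelope and late differentiation genes 17 rose and 7 fell; their median was 0.37, while camera, which compares them with all other genes, gave the direction down without passing (adjusted p = 0.653). Krt1, a keratin of suprabasal cells, rose from 184 ± 42.5 to 2001 ± 211 FPKM (log2 fold change 3.46, SE 0.18), whereas involucrin (Ivl) fell from 129 ± 18.4 to 51.3 ± 7.41 FPKM and transglutaminase 3 (Tgm3) from 76.2 ± 7.96 to 33.6 ± 2.69 FPKM. Of 18 basal keratinocyte genes 9 rose and 2 fell, with Itga6 going from 12.8 to 29.6 FPKM; without control P36 replicate 2 only 5 were called and without DKO P36 replicate 2 only 4. The list's camera call (adjusted p = 0.0307) was lost without DKO P36 replicate 2 (0.0534) and with an estimated correlation (adjusted p = 0.446). None of 30 cell cycle genes was called by limma at P36; the smallest p-values belonged to Pcna (adjusted p = 0.164) and Cdk1 (adjusted p = 0.175).

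Stress, antimicrobial and immune cell genes rose together at P36. Of 24 stress and wound genes 13 rose and 1 fell, including Krt6b, a keratin of wounded epidermis, from 2.79 to 64.4 FPKM, and the gelatinase Mmp9, from 0.577 to 11.6 FPKM (camera adjusted p = 0.00131, adjusted p = 0.446 with an estimated correlation). Of 19 antimicrobial genes 10 rose and 1 fell, with Saa3 going from 3.81 to 153 FPKM (adjusted p = 0.399 with an estimated correlation); without any 1 of the 3 libraries labelled DKO, 7 were called. Of 16 cytokine and chemokine genes 9 rose and 1 fell, among them Il33 and Csf1 (adjusted p = 0.32 with an estimated correlation); 6 were called without DKO P36 replicate 1 or replicate 3. Of 9 T cell genes 6 rose (adjusted p = 0.298 with an estimated correlation). Of 18 interferon response genes 5 rose and 11 did when adjusted over the list alone (adjusted p = 0.605 with an estimated correlation, and fry did not pass, adjusted p = 0.11). Only 2 interferon genes were called without control P36 replicate 1 and 3 without control P36 replicate 2 or replicate 3, while 10 were called with the replicate number as a block. DKO P36 replicate 2 stood apart with a mean log2(FPKM + 1) of 3.62 against 2.59 and 2.27. All 15 macrophage, neutrophil and mast cell genes rose, with a median of 1.88 (adjusted p = 0.288 with an estimated correlation; 9 were called without the genes that stood out in DKO 6mo replicate 3, which takes out list members), and 11 of 15 Langerhans cell and antigen presentation genes rose, with H2-Ab1 going from 50.5 to 130 FPKM (adjusted p = 0.288 with an estimated correlation).

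Markers of tissues below the epidermis were higher in the same P36 libraries. Of 15 skeletal muscle genes 14 rose, with a median of 3.13, and 9 did without DKO P36 replicate 1 or replicate 2 (adjusted p = 0.356 with an estimated correlation). The mean log2(FPKM + 1) of the muscle list was 4.83, 4.05 and 2.97 in the libraries labelled DKO and 1.04, 0.98 and 1.48 in control. Of 17 dermal fibroblast genes 10 rose (adjusted p = 0.334 with an estimated correlation), and of 14 smooth muscle and endothelium genes 11 rose (adjusted p = 0.288 with an estimated correlation). Without the genes that stood out in DKO 6mo replicate 3, 2739 genes were called at P36. That setting takes genes out of the fit, and 219 genes of the main call were then not tested. The count therefore does not show what caused the calls. These rises stand beside those of the lipid, stress and immune lists, which can therefore not be assigned to the epidermis alone.

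**Figure D2:**
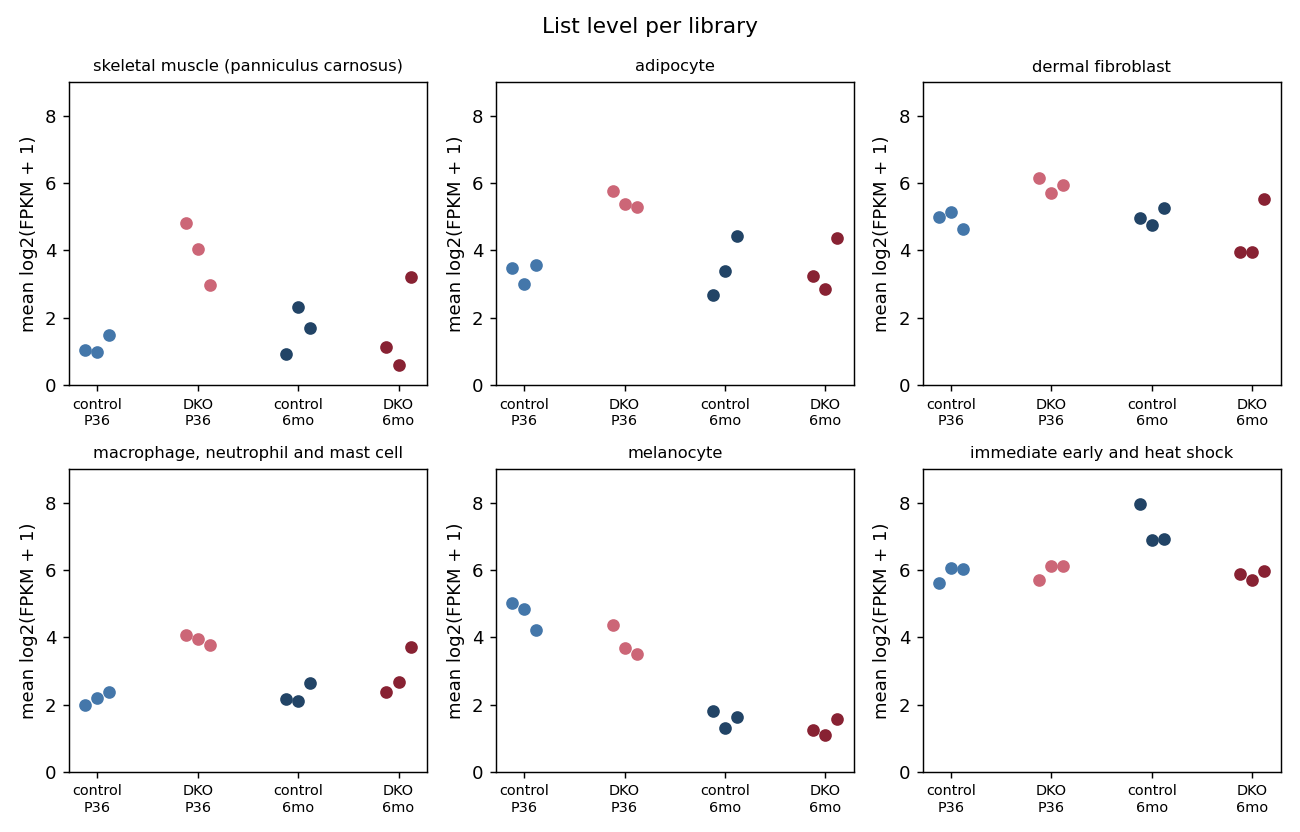
Mean log2(FPKM + 1) of 6 gene lists in each of the 12 libraries by group; each point is a library. At P36 the skeletal muscle list is at 2.97 to 4.83 in the libraries labelled DKO and at 0.98 to 1.48 in control, and at 6 months control replicate 1 has the highest immediate early level, 7.97.

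At 6 months, the upper follicle, sebaceous gland, protease and stress lists rose and the bulge, hair matrix, dermal papilla and basal lists fell in the libraries labelled DKO, all at the preset correlation. None of these calls held with an estimated correlation (adjusted p at least 0.258), and all of them held with fry (adjusted p at most 0.00853). Krt15, a keratin of basal and bulge cells, fell from 1644 ± 53.4 to 181 ± 16.6 FPKM (log2 fold change −3.18, SE 0.11). Krt79, a keratin of the infundibulum and sebaceous duct, rose from 151 ± 27.7 to 1011 ± 113 FPKM (2.74, SE 0.16). Some lists share members, so their calls are not independent. Krt15 is in the bulge and basal lists, Krt79 in the upper follicle and sebaceous gland lists, and Klk6 and Cst6 in the upper follicle and protease lists. Stfa3 rose from 12.9 ± 9.74 to 1086 ± 349 FPKM (6.49, SE 0.49), and Ifitm6 showed the largest fall, from 168 ± 26.8 to 0.453 ± 0.188 FPKM (−6.86, SE 0.15). In all, 5207 of 12594 genes were called, 2918 higher and 2289 lower, of which 567 and 732 changed by at least 1 on the log2 scale. Totals without keratin and cornified envelope genes gave 1862 higher and 3386 lower and moved the median of all genes from 0.04 to −0.13, so that the balance of higher against lower genes depends on the scaling. No named gene changed sign, but this shift is smaller than the smallest called change (0.26), so a called gene could hardly do so.

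Follicle genes divided by compartment at 6 months. Of 21 bulge and outer root sheath genes 12 fell and 4 rose (14 and 5 adjusted over the list alone; camera adjusted p = 0.0007, adjusted p = 0.471 with an estimated correlation). Fgf18, a growth factor of the resting follicle, went from 24.2 ± 5.64 to 0.123 ± 0.0751 FPKM. Of 23 hair matrix and signalling genes 17 fell and 2 rose, including Wnt3, from 39.3 to 5.68 FPKM, and Bmp4, from 21.6 to 3.89 FPKM (adjusted p = 0.258 with an estimated correlation). Of 8 dermal papilla genes 7 fell, including Wif1 and Rspo3 (adjusted p = 0.471 with an estimated correlation). Lists of other cell types also changed in the same libraries. Of 5 red blood cell genes 4 rose and 0 fell, with a median of 1.51 (camera adjusted p = 0.0464). That call was lost without control 6mo replicate 1 (0.0836), with a pseudocount of 0.1 (0.0564) and with an estimated correlation (0.471). Of 5 Schwann and Merkel cell genes 4 fell, with a median of −1.71 (camera adjusted p = 0.0026, adjusted p = 0.471 with an estimated correlation). The smooth muscle and endothelium list had a median of −0.41 (camera adjusted p = 0.0149, 0.0506 without DKO 6mo replicate 2, 0.0561 with totals without keratin and cornified envelope genes, and adjusted p = 0.672 with an estimated correlation; fry did not pass, adjusted p = 0.06). Of 14 hair shaft genes measured at 6 months 5 fell and 0 rose, with a median of −0.51 (camera adjusted p = 0.023). The list call was lost without DKO 6mo replicate 1 (0.109), with no filter on low values (0.493) and in the joint fit of all 12 libraries (0.45). It was also lost with totals without keratin and cornified envelope genes (0.0923) and with an estimated correlation (0.501), and fry did not pass (adjusted p = 0.0829). In the other direction, 8 of 10 utricle and upper follicle genes rose and 0 fell, with Klk6 going from 9.27 to 138 FPKM and Cst6 from 107 to 465 FPKM (camera adjusted p = 2.5e-05, adjusted p = 0.27 with an estimated correlation). Of 19 sebaceous gland markers 13 rose and 1 fell, with Mgst1 going from 93.4 to 411 FPKM (adjusted p = 0.471 with an estimated correlation).

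Barrier genes also changed at 6 months. Of 51 cornified envelope and late differentiation genes 29 rose and 9 fell; camera's adjusted p was 0.0149, and was 0.0575 without DKO 6mo replicate 1, 0.0519 without DKO 6mo replicate 2, 0.108 with the filter at 5 FPKM and 0.728 with an estimated correlation, and fry did not pass (adjusted p = 0.101). Sprr4 rose from 20.2 ± 8.8 to 398 ± 104 FPKM and caspase 14 (Casp14), a protease of the cornified layer, from 88.8 ± 22.4 to 498 ± 66.5 FPKM, while filaggrin 2 (Flg2) fell from 574 ± 79.4 to 138 ± 15.7 FPKM and Krt77 from 3549 ± 544 to 609 ± 120 FPKM. Of 21 proteases and inhibitors 14 rose and 2 fell (adjusted p = 0.471 with an estimated correlation). Of 36 ceramide and lamellar lipid genes 13 rose and 4 fell, with the elongase Elovl7 going from 23.2 to 113 FPKM (adjusted p = 0.501 with an estimated correlation). Of 24 cholesterol genes 11 rose and 1 fell, with Idi1 going from 62.7 to 229 FPKM (adjusted p = 0.501 with an estimated correlation). Of 22 junction genes 7 fell and 3 rose, among them Cldn23, from 53.1 to 15.6 FPKM, without a list call (camera adjusted p = 0.0564). Of 18 basal keratinocyte genes 12 fell and 1 rose, with Col17a1, a hemidesmosome collagen, going from 388 to 122 FPKM (adjusted p = 0.471 with an estimated correlation).

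Of 21 stress and wound genes 13 rose and 0 fell at 6 months, with Krt16 going from 40.9 to 333 FPKM (adjusted p = 0.258 with an estimated correlation). Of 18 antimicrobial genes 12 rose and 0 fell, with lipocalin 2 (Lcn2) going from 3.93 to 81.6 FPKM (adjusted p = 0.2 with an estimated correlation). Of 22 immediate early and heat shock genes 14 fell and 1 rose, with Dusp1 going from 347 ± 130 to 44.9 ± 5.11 FPKM (adjusted p = 0.471 with an estimated correlation). Control 6mo replicate 1 stood apart in this list, with a mean log2(FPKM + 1) of 7.97 against 6.9 and 6.91 in the other control libraries. The libraries labelled DKO stood at 5.69 to 5.96, near both genotypes at P36 (5.62 to 6.12), and the control libraries at 6 months stood above all of these. Age follows the table, so these levels do not tell which genotype departed. Of 15 Langerhans cell and antigen presentation genes 7 fell and 3 rose; without DKO 6mo replicate 2 only 5 were called, and the list did not pass (camera adjusted p = 0.0573). In the main limma fit no muscle or adipocyte gene was called at 6 months. With the replicate number as a block, 2 adipocyte genes were called higher, Lpl (1.19, limma adjusted p = 0.0445) and Plin4 (0.50, limma adjusted p = 0.0451), and 1 was in the joint fit. The muscle list reached 3.22 in DKO 6mo replicate 3 against 1.12 and 0.6 in the other libraries labelled DKO. Of 17 fibroblast genes 2 fell, and 12 fell without DKO 6mo replicate 3; of 14 smooth muscle and endothelium genes 5 fell, and 8 without that library. Without that library and control 6mo replicate 1, 5413 genes were called, 2545 higher and 2868 lower, and 10 muscle and 6 adipocyte genes were called lower; without DKO 6mo replicate 3 alone, 2 muscle genes were.

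**Figure D3:**
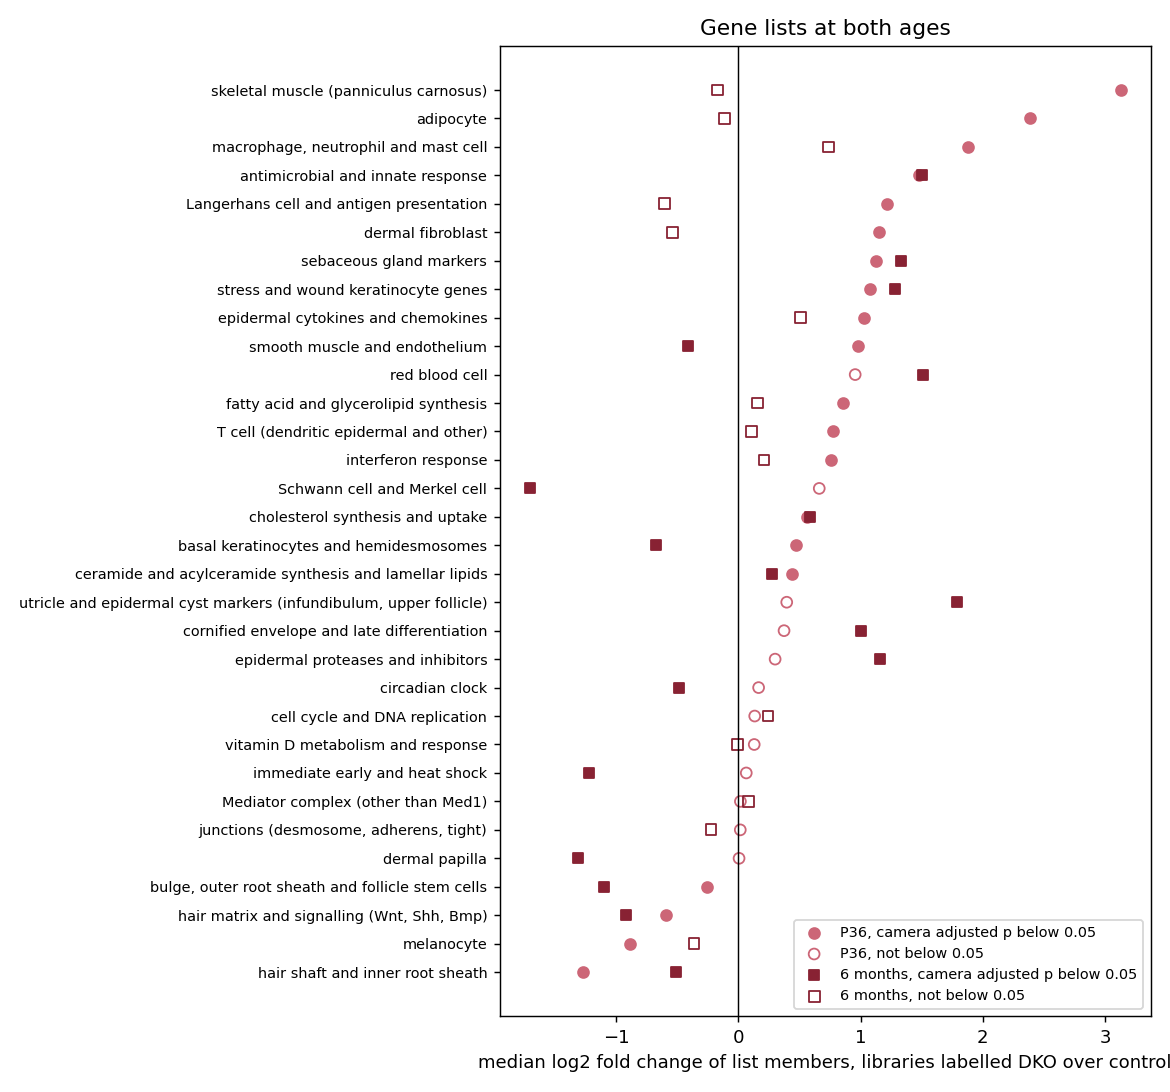
Median log2 fold change (libraries labelled DKO over control) of each of 32 gene lists at P36 (circles) and 6 months (squares); filled symbols have a camera adjusted p below 0.05 at the preset correlation. The hair shaft list lies at −1.27 at P36, the skeletal muscle list at 3.13 at P36, and the utricle list at 1.79 at 6 months.

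Genes linked to the targets were examined as lists. Of 31 other Mediator genes 1 rose and 1 fell at P36, where 0 were called without control P36 replicate 2 or DKO P36 replicate 1 and 1 without each other library. At 6 months 7 rose and 3 fell, where 5 were called without control 6mo replicate 2 and 6 without control 6mo replicate 3, DKO 6mo replicate 2 or DKO 6mo replicate 3. Of 10 genes of vitamin D metabolism and response 1 rose at P36, and of 11 at 6 months 2 rose and 2 fell, with the cystatin gene Cst6 among them; the list had a median of −0.01 and a mean of 0.10, and camera's direction was down (adjusted p = 0.695). Of 18 circadian clock genes 8 fell and 1 rose at 6 months (camera adjusted p = 0.0146, 0.101 without control 6mo replicate 1, and adjusted p = 0.471 with an estimated correlation).

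The genotype difference depended on age for 4631 of 13280 genes, 1827 with a more positive and 2804 with a more negative difference at 6 months. Of these genes 197 were below 1 FPKM in both genotypes at 6 months, 21 hair shaft genes among them, and 167 were so at P36; they have little room for a fall at that age. The tables of the 2 ages were made separately and age follows the table, so a difference between tables and one between ages cannot be separated. Hair gene activity differed as well: in control the hair shaft list had a mean log2(FPKM + 1) of 8.17 to 8.71 at P36 and 0.87 to 1.24 at 6 months. The state of the hair follicles can therefore not be separated from age either. Tmprss11e, a serine protease, stood at 16.7 and 12.4 FPKM in control and the libraries labelled DKO at P36 and at 0.553 and 14.6 FPKM at 6 months (interaction log2 3.75, SE 0.26, limma adjusted p = 1.3e-05). The tight junction gene Cldn3 stood at 29.2 and 19.1 FPKM at P36 and at 19.4 and 0.377 FPKM at 6 months (−3.30, SE 0.20). Il31ra, an interleukin 31 receptor subunit, stood at 0.78 and 0.953 FPKM and then at 23.6 and 0.563 FPKM (−4.08, SE 0.26). Il31ra is one of the genes below 1 FPKM in both genotypes at P36. The scale leaves it little room for a fall there, so its value does not show an effect that differs with age. Of the 12047 genes tested at both ages, 602 rose at both, where independent lists would share 512, and 174 fell at both, where they would share 85.2. Others went in opposite directions: 365 rose at P36 and fell at 6 months, where independent lists would share 390. A further 79 fell at P36 and rose at 6 months, where they would share 112. Across genes, the log2 fold changes of the ages had a Pearson r of 0.205 and a Spearman rho of 0.093. The stefin genes Stfa1 and Stfa3 rose at both ages with no interaction call (adjusted p = 0.539 and 0.401).

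Between the ages, hair genes fell in both genotypes. In control, 8386 of 13280 genes differed, 4682 higher and 3704 lower at 6 months, and 46 of 48 hair shaft genes fell, with Krt73 going from 1022 ± 65.7 to 0.04 ± 0.0458 FPKM (adjusted p = 0.326 for the list with an estimated correlation). Of 30 cell cycle genes 27 fell and of 15 Langerhans cell genes 13 rose in control (adjusted p = 0.662 and 0.334 with an estimated correlation). In the libraries labelled DKO 7969 genes differed, 3716 higher and 4253 lower, with 47 of 48 hair shaft genes lower and Krt35 going from 296 ± 78.2 to 0.0867 ± 0.15 FPKM (adjusted p = 0.356 for the list with an estimated correlation). Rora, a nuclear receptor gene, rose in both, from 6.2 to 36.7 FPKM in control and from 11.5 to 42.9 FPKM in the libraries labelled DKO.

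In the authors' deposited table, 11891 of 17004 genes with a test at P36 and 13622 of 16902 at 6 months had a q-value below 0.05. These q-values lay below the authors' own p-values for 64.8% and 76.3% of genes and did not exceed 0.351 and 0.237, so a q-value below 0.05 is a looser criterion than the adjusted p used here. The larger counts do not come from the q-values alone. The authors' p-values were 1.4e-82 for Vdr at P36 and 9.74e-14 for Med1 at 6 months, neither of them called in the main limma fits. By the authors' q-values Vdr was higher and Med1 lower at both ages. With a change of at least 2-fold as well, the authors' deposited table held 2157 higher and 713 lower genes at P36 and 1552 higher and 2053 lower genes at 6 months.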

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

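Of the tests in this part, those for a lower keratinocyte share, for tissue from below the epidermis, for a library in the wrong group, for exchanged labels and for other splits of the samples, and the count of genes below 1 FPKM, were chosen after the results were seen. The genotype difference shared by both ages was removed before genotype was reassigned within the ages. Of 100 such assignments, the real one included, 1 gave as many as the 4631 genes whose genotype difference depended on age. That rank argues against a chance assignment of these libraries. It does not cover chance differences between animals, since the labels do not say that the replicates are separate animals. The other draws move the difference between ages into the spread within groups, which lowers their counts. The highest other draw gave 136; it was one of 22 other draws that keep the real genotype split at 1 age, and the remaining draws gave at most 16. These draws do not separate age from a difference between the tables. For P36 (2949 genes, highest other split 1), 6 months (5207, highest other 0), age in control (8386, highest other 0) and age in the libraries labelled DKO (7969, highest other 0), 1 of 10 splits gave as many genes, and 10 splits are too few for a share below 0.05.

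These results differed between the ages by the test of the interaction (6 months minus P36). For lists, the median interaction log2 value was 0.67 for proteases, −0.55 for fatty acid synthesis, −1.10 for bulge, 1.08 for utricle, −1.32 for basal keratinocytes, −0.41 for circadian clock and −1.25 for immediate early genes. It was −1.85 for Langerhans cells, −1.29 for macrophages, neutrophils and mast cells, 0.74 for melanocytes, −1.47 for fibroblasts, −1.07 for dermal papilla, −2.71 for adipocytes, −2.71 for skeletal muscle, −1.37 for smooth muscle and endothelium and −1.08 for Schwann and Merkel cells. It was 1.35 for hair shaft, where 30 of 48 members and 21 of the 27 called members are below 1 FPKM in both genotypes at 6 months. The scale leaves these members little room for the fall seen at P36, so this value does not show an effect that differs with age. Of 14 melanocyte members 5 are that low at 6 months, with 1 of the 3 called members among them. The mean log2(FPKM + 1) of the melanocyte list in control was 4.23 to 5.03 at P36 and 1.3 to 1.8 at 6 months. The melanocyte value is therefore open to the same limit. None of these 17 list calls held with an estimated correlation (adjusted p at least 0.608). With fry, the macrophage, melanocyte, fibroblast and skeletal muscle lists did not pass (adjusted p = 0.0649, 0.331, 0.0738 and 0.0649), and the others did. For genes, the interaction log2 value was 1.82 for Crot, 2.66 for Smpdl3b, 3.61 for Elf5, 3.75 for Tmprss11e, −3.30 for Cldn3, −4.08 for Il31ra, −3.11 for Dab1 and −3.11 for Tgfbi. Il31ra was below 1 FPKM in both genotypes at P36, so its value has the same limit as that of hair shaft. Among 27 genes named at both ages it was −3.82 for Krt75, −3.54 for Acta2, −1.42 for Bmp2, −1.30 for Bmp6, −2.16 for H2-DMb1, −3.05 for Pmp22, −2.40 for Thy1, −2.48 for Vim, 1.13 for Krt79 and −1.54 for Plin4.

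Markers of muscle, fat, connective tissue and vessels were higher in the libraries labelled DKO at P36. A lower share of keratinocytes would by itself raise all other cell types alike. The medians of the skeletal muscle and melanocyte lists differed by 4.02, with a joint spread of 1.48, which argues against it as the only cause. Both lists were chosen after their medians were seen. Melanocyte genes fell beside the hair shaft and hair matrix lists (medians −1.27 and −0.59), so the comparison cannot tell whether a lower share contributes. Tissue from below the epidermis that came off with the sheet may contribute: 14 of 15 skeletal muscle genes (median 3.13) and 9 of 11 adipocyte genes (median 2.385) rose. The 5 most abundant fibroblast genes do not decide it. They had a median log2 fold change of 0.52 with a median SE of 0.29. Vim was called higher (1.24, limma adjusted p = 0.000416), and Col3a1, Sparc, Col1a1 and Col1a2 stood at 0.79, 0.52, 0.39 and 0.16 without a call. A change in these tissues with genotype is the biological alternative and was not tested.

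Immediate early genes were lower in the libraries labelled DKO at 6 months, and control 6mo replicate 1 had the highest level. That library alone is an unlikely cause: without it, 16 members were called lower and the list test had an adjusted p of 2.98e-05 at the preset correlation. The libraries labelled DKO at 6 months had a mean log2(FPKM + 1) of 5.69 to 5.96, near both genotypes at P36 (5.62 to 6.12). The control libraries at 6 months stood at 6.9 to 7.97, above all of these. Age follows the table, so the levels do not tell whether control or the libraries labelled DKO departed. Between the ages, 14 of 22 members rose and 0 fell in control, against 3 and 5 in the libraries labelled DKO. A difference in how the skin was handled that follows genotype, and an effect of genotype itself, stay open and were not tested.

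Vdr was not lower in the libraries labelled DKO. A single library in the wrong group is argued against, since 0 of 12 libraries correlated better with the other genotype of their age than with their own. An exchange of the labels is argued against at P36 by Med1, with a log2 fold change of −0.55 (adjusted p = 0.0083); at 6 months Med1 was not called (−0.26, adjusted p = 0.13), except with totals without keratin and cornified envelope genes (−0.44, adjusted p = 0.0342). A transcript that persists after part of the gene is removed could give such values and stays open, because a single FPKM value per gene cannot show it.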

How the results depend on the processing

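Median-ratio scaling, the filter at 5 FPKM and both exclusions described as added were chosen after the data were seen. The depth of the libraries is unknown, so what depth limits could not be assessed, and alternatives that need counts (other size factors, count filters, DESeq2 and limma-voom) were not run. With a log2 fold change of at least 1 required as well, the counts were 917 at P36, 1299 at 6 months, 1926 for the difference between ages, 3000 for age in control and 2094 for age in the libraries labelled DKO, because the criterion is stricter by construction. Leaving out each library in turn gave 1662 to 2660 genes at P36, 3682 to 4893 at 6 months, 3603 to 4843 for the difference between ages, 7629 to 7887 for age in control and 6840 to 7775 for age in the libraries labelled DKO. The low values at P36 came without DKO P36 replicate 2 (1662) and DKO P36 replicate 3 (1697); the cause was not tested beyond the smaller number of samples. Every other setting kept these counts within 1.5 times.

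Totals without keratin and cornified envelope genes moved the median log2 value of all genes from 0.04 to −0.13 at 6 months, from −0.08 to −0.21 for the difference between ages and from 0.10 to 0.22 for age in control. The split became 1862 higher and 3386 lower at 6 months and 1241 higher and 3465 lower for the difference between ages. Over 3662 values of named genes under the alternatives, 0 changed sign, and 121 lost and 11 gained a call. The smallest called change was 0.26 at both ages, larger than any of these shifts, so a called gene could hardly change sign by them. All 87 list calls made at the preset correlation were lost with an estimated correlation, and 0 changed direction in any setting. With fry, 78 of them held and 9 were lost. The estimated correlation did not even pass the hair shaft list between the ages in control (46 of 48 lower, adjusted p = 0.326). A loss with it therefore does not show that a list is unchanged. Med1 at 6 months was called lower with those totals (−0.44, adjusted p = 0.0342).

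The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.135, −0.058 and −0.115 at P36 and at −0.063, 0.032 and 0.183 at 6 months. With the replicate number as a block, 2607 genes were called at P36, 4862 at 6 months, 4223 for the difference between ages, 7868 for age in control and 7348 for age in the libraries labelled DKO.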

Other observations

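The test of neighbouring genes below was planned before its result was seen, and the genes of this part were chosen after their values were seen. The families here were not tested as groups, and only single genes are described. Gasdermin C (Gsdmc), a pore-forming protein, rose from 0.467 to 27.2 FPKM at P36 and from 0.39 to 55.0 FPKM at 6 months (log2 fold changes 4.27 and 5.24). The serpin genes Serpinb3a, Serpinb3b and Serpinb3c rose at both ages; Serpinb3a went from 0.197 to 15.7 FPKM at P36 and from 1.26 to 77.7 FPKM at 6 months, and Serpinb3b from 4.73 to 42.8 FPKM and from 28.7 to 153 FPKM. Stfa2 was not called at P36 (log2 fold change −0.34, adjusted p = 0.46) and rose from 0.967 to 41.1 FPKM at 6 months. Stefin A, Sprr2 and Serpinb3 genes have near-identical copies, so single members of these families are uncertain.

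Within the Ifitm family, which encodes interferon-induced membrane proteins, the members called at P36 rose and those called at 6 months fell. At P36 Ifitm1, Ifitm2 and Ifitm3 rose by 2.62, 1.13 and 1.81, and at 6 months Ifitm6 fell by 6.86 and Ifitm2 by 0.84 on the log2 scale. At 6 months Ifitm1 and Ifitm3 were not called (log2 fold changes 0.53 and −0.01, adjusted p = 0.367 and 0.969), nor was Ifitm6 at P36 (−1.40, adjusted p = 0.063). The protease inhibitor Wfdc3 fell by 1.29 at P36 and by 5.92 at 6 months, while Wfdc12 rose by 2.56 and 2.87; Wfdc5 rose by 1.22 at P36 and was not called at 6 months (−0.32, adjusted p = 0.213).

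A hypothesis that neighbouring genes of different families rise together was not borne out. At 6 months, 31 pairs of neighbours both rose by at least 1 on the log2 scale, against a median of 24, a highest value of 43 and an upper bound of 33 over 1000 shuffles (permutation p = 0.08, one-sided). Families were told apart only by the start of the symbol, so some of the pairs, such as Csta3 and Stfa1, are still relatives.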
